A study of Mus musculus with 6 samples.

How the data were processed

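RNA was profiled from submandibular glands of ICR mouse embryos at embryonic day 13 (E13), with 3 libraries from control glands and 3 from glands treated with blebbistatin. Blebbistatin is a small molecule that blocks the ATPase of non-muscle myosin II. The dose, the length of treatment, the vehicle and the number of glands per library are not given in the sources used here. The title of the series speaks of epithelial buds, whereas the tissue label of every sample names the gland. Per the labels' protocols, RNA was purified on RNeasy columns and libraries were made with the TruSeq RNA kit of Illumina, and whether the libraries kept strand is not given in the sources used here. Nothing in the labels says that the 3 libraries of a group came from separate cultures or litters. The p-values of genes, transcripts and transcript shares therefore measure the spread between these libraries, which may be technical.

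Per the submitters' processing notes, the tools were TopHat2 2.0.13, Bowtie2 2.2.3 and Cufflinks 2.2.1, and the genome build was mm10. The deposited gene and transcript tables hold FPKM (fragments scaled by the length of the transcript in kilobases and by the total of the library) as the authors computed them, per the file headers, for the RefSeq annotation that is deposited beside them. Transcript lengths and exon coordinates were taken from the deposited files, so that coordinates are mm10, counted from 1. Columns were matched to samples by name. The columns abbreviated BB were taken as blebbistatin, and a column without a number was taken as replicate 1, since replicates 2 and 3 carry theirs. The gene table held 24067 genes, of which 18408 were above 0 in at least 1 library. A total of 131 genes had no symbol there, and symbols were then taken from the transcript table through the Entrez number where it had one. The gene value was the sum of its transcripts to within 0.1% for all but 116 genes.

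FPKM values are scaled to the total, so a count model was not used. Genes with a mean FPKM of at least 1 over the 6 libraries (11540 genes) were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using empirical Bayes moderation with a mean-variance trend. The treatment was the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Fold changes are on the log2(FPKM + 1) scale, blebbistatin minus control, and understate the change of genes with low values. Means are given with the SD over 3 libraries, and log2 fold changes with the moderated standard error (SE).

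The main tests, 35 gene lists and the rule for naming genes were fixed before the data were examined. A list was tested with camera at an inter-gene correlation of 0.01 when at least 4 members were tested, and p-values were adjusted over the 29 lists that met this. The same test with an estimated correlation and fry were run beside it. At the fixed correlation, camera compares members with other genes and takes genes as nearly independent. Its p-values therefore do not measure how far the libraries of a group agree. The lists of endothelial, neuronal, glial, leukocyte and skeletal muscle genes had too few tested members, and the list of sex-linked genes served only to check samples. A list score is the mean over tested members of the deviation of log2(FPKM + 1) from the mean of the 6 libraries, and group differences in it were tested with a two-sided exact permutation test. With 3 libraries against 3 that test cannot give a p below 0.1.

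Transcripts with a mean FPKM of at least 1 (14460 of 33819) were tested with limma in the same way. The share of each transcript in the summed FPKM of its gene was tested with limma on the arcsine square root scale. This test took genes with at least 2 transcripts, a mean sum of at least 5 FPKM and a value above 0 in every library, and transcripts with a mean share between 0.05 and 0.95 (4997 transcripts of 2103 genes).

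The named genes are the 12 genes per direction with the largest change among those past the threshold with no overlap between the groups, filled up by smallest unadjusted p. Genes of small RNAs, genes with transcripts under 300 nt, Y-linked genes and Xist were left out of this rule. Added to these were Myh9, Myh10 and Myh14, up to 4 members of smallest p for each list described, and the 6 transcripts of smallest p in each transcript test.

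On simulated data built from the 11540 tested genes, the gene test recovered 85% of 100 genes changed by a log2 of 1 and 99% of 100 genes changed by a log2 of 2. In that simulation 12 of 196 calls were false, and with no gene changed there were 0 calls. An adjusted threshold is easier to reach when many genes change, and in the data only 9 genes passed. The recovery of 85% therefore does not carry over to the data. There Wfdc18 (log2 fold change -1.54) and Cpe (1.24), for example, did not pass. A simulated shift of 1 list of 24 genes was recovered with 0 of the other lists called. The noise was drawn separately for each gene, so the simulated genes of a list were not correlated. How the list test behaves with correlated members, such as those of the mitosis list (estimated correlation 0.867), was not simulated. In the simulation of the transcript test 95% of 200 transcripts changed by a log2 of 2 were recovered, with 10 false calls. In that of the shares 95.5% of 200 shares changed by 0.5 on the arcsine scale were recovered, with 15 false calls. In the data the share of smallest p differed by -0.31 on that scale (Kifc3). Recovery of smaller changes was not simulated for either test.

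Depth was estimated from low values. For genes with 1 transcript of over 2000 nt, FPKM times length fell on steps that match single fragments, and 86.6 to 90.4% of low values lay within 0.15 of a whole step, where evenly spread values would give 30%. The steps correspond to 27300000 to 33200000 fragments per library. At 2 kb, 1 FPKM then stands for 54.6 to 66.5 fragments. Since the steps depend on the effective length used by Cufflinks, these are estimates, and no counting interval was computed from them.

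The alternatives tried were a pseudocount of 0.1, no filter and a filter of 5 FPKM, median-of-ratios rescaling, quantile normalization, the replicate number as a block, no variance trend, array weights, small RNA genes left out, and each library left out in turn. For the shares they were a gene minimum of 1 or 20 FPKM and a log ratio in place of the arcsine. Removal of a trend with transcript length (loess, span 0.5), alone and with the block, was added after seeing the data, because the libraries differed in such a trend. Figures were drawn with matplotlib.

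Of the 4 families of genes with a shared symbol stem that passed, 1 is not reported here.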

Results

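The transcriptome of the E13 mouse submandibular gland, a branching epithelial organ, was compared between 3 control libraries and 3 libraries from glands treated with blebbistatin, which inhibits the motor activity of non-muscle myosin II. The comparison asks which transcripts differ when myosin II is blocked. Estimated depth was 28000000, 33200000 and 28200000 fragments for control replicates 1 to 3, and 27900000, 27900000 and 27300000 for blebbistatin replicates 1 to 3. Between 11453 and 11592 genes reached 1 FPKM per library, and pairs of libraries correlated across genes with Pearson's r from 0.971 to 0.983, where genes are not independent replicates. Epcam, an epithelial adhesion molecule, stood at 424 ± 21.3 FPKM in controls and 385 ± 18.3 in treated libraries (SD, n = 3), whereas Col1a1, the main collagen of mesenchyme, lay between 0.588 and 3.06 FPKM in the 6 libraries. The median member of the mesenchymal, endothelial and neuronal lists had a mean of 0.779, 0.0489 and 0.121 FPKM. Whether whole glands or epithelial buds were profiled is not given in the sources used here. The libraries did not separate by group on the first principal component (29.0% of variance), where blebbistatin replicate 1 and control replicate 3 lay at opposite ends. On the second (25.3% of variance) they did, with controls at 23.6, 5.72 and 0.182 and treated libraries at -7.93, -2.55 and -19.1.

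Blebbistatin was accompanied by a rise of the matrix glycoprotein tenascin C and a fall of type II collagen. Tnc rose from 4.34 ± 1.31 to 16.1 ± 2.76 FPKM (SD, n = 3), a log2 fold change of 1.69 ± 0.19 (SE, adjusted p = 0.0377, limma). Slc35f1, a solute carrier family member, rose from 3.05 ± 0.30 to 6.95 ± 0.85 FPKM, Lurap1l from 8.70 ± 0.81 to 17.8 ± 2.39 FPKM, and 1810010H24Rik from 5.80 ± 0.22 to 12.01 ± 0.72 FPKM. Col2a1, the type II collagen chain, fell from 169 ± 12.2 to 81.8 ± 13.6 FPKM (log2 fold change -1.05 ± 0.13, adjusted p = 0.0461). Olfml3, a secreted olfactomedin-domain protein, fell from 8.48 ± 0.71 to 3.00 ± 0.82 FPKM (log2 fold change -1.26 ± 0.15, adjusted p = 0.0379). Fam101a fell from 5.07 ± 0.36 to 2.22 ± 0.26 FPKM, and Ptk2b, which encodes the focal adhesion kinase relative Pyk2, from 10.9 ± 0.82 to 5.60 ± 0.46 FPKM. For each of these 8 genes the 3 treated libraries lay all above or all below the 3 controls.

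**Figure D1:**
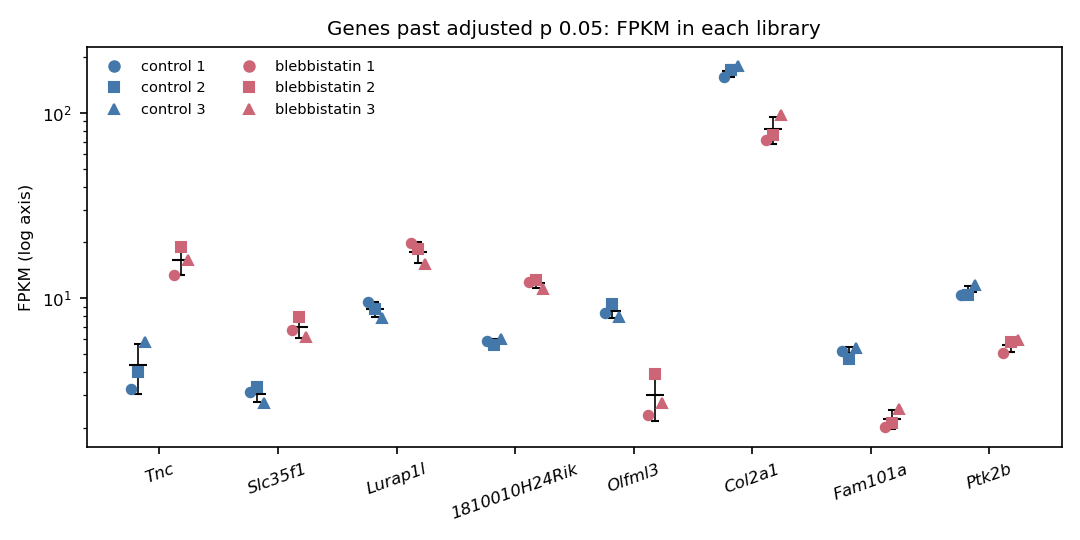
FPKM (log axis) of the 8 named genes past an adjusted p of 0.05 in each library, with control libraries in blue, blebbistatin libraries in red, the marker shape giving the replicate number, and bars giving mean and SD (n = 3). The groups do not overlap for any of the 8 genes, and Tnc shows the highest fold, 3.23 on the log2(FPKM + 1) scale.

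In all, 9 of 11540 genes passed an adjusted p of 0.05 (limma), 4 higher and 5 lower, and 4 of these had an absolute log2 fold change of at least 1 (1 higher, 3 lower). The ninth was the microRNA gene Mir8094, which the naming rule leaves out and which was singled out after its values were seen. It was at 40.5, 57.9 and 67.8 FPKM in the controls and was listed at 0 in all 3 treated libraries. Its annotated transcript is 117 nt long and lies on the same strand within exons of Ddx39b, which stood at 237 ± 4.05 and 234 ± 8.81 FPKM, so that both can share fragments and the value of Mir8094 is uncertain. At an unadjusted p under 0.05 there were 1080 genes (515 higher, 565 lower) where 577 are expected by chance, and at an adjusted p under 0.1 there were 90 (31 higher, 59 lower). The groups did not overlap for 1648 genes, 14.3% of those tested, where chance gives 10%. The count of 9 became 1 without control replicate 1, 2 without control replicate 2, 2 without blebbistatin replicate 1, 4 without blebbistatin replicate 2 and 19 without blebbistatin replicate 3, and each of the 8 named calls was lost without control replicate 1, control replicate 2 or blebbistatin replicate 1. The count was 1 with no filter on low values, 27 with a minimum of 5 FPKM, 14 after quantile normalization (6 higher, 8 lower), 57 with array weights and 2 after median-of-ratios rescaling (1 higher, 1 lower, with 0 higher and 1 lower at an absolute log2 fold change of at least 1). The 1 gene left with no filter was Mir8094, and the 2 left after median-of-ratios rescaling were Mir8094 and 1810010H24Rik. Col2a1 was lost after quantile normalization as well. With the replicate number as a block, a pairing that the labels do not state, 144 genes passed (53 higher, 91 lower). Removal of the trend with transcript length, added after the data were seen, gave 18 (9 higher, 9 lower).

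On mm10, Tnc lies on chromosome 4 from 63959785 to 64047015, Slc35f1 on chromosome 10 from 52690501 to 53111622, Lurap1l on chromosome 4 from 80910686 to 80954301, and 1810010H24Rik on chromosome 11 from 107028223 to 107030442. Col2a1 lies on chromosome 15 from 97975602 to 98004724, Olfml3 on chromosome 3 from 103735394 to 103738001, Fam101a on chromosome 5 from 125003475 to 125012547, and Ptk2b on chromosome 14 from 66153257 to 66281052. No exon of these 8 genes overlaps an exon of another gene in the deposited annotation. Mir8094 lies on chromosome 17 from 35251289 to 35251405. Among genes named further on, exons of Crim1, Ppfibp2, Tagln, Esrp2, Cldn3, Col9a3 and Ankrd37 overlap those of a gene on the opposite strand, and without a stated strand their fragments may be shared.

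The next genes by unadjusted p did not pass the threshold, with adjusted p between 0.0578 and 0.0727. Those with higher values under blebbistatin were Crim1 (log2 fold change 0.76 ± 0.10, SE), Lipg (0.56 ± 0.08), Cpe (1.24 ± 0.18), Cldn8 (0.75 ± 0.11), Rnd3 (0.83 ± 0.12), Plekhh2 (0.95 ± 0.14), Cyr61 (1.06 ± 0.16) and Pls3 (0.58 ± 0.09). Pls3 is an actin-bundling plastin, and Cyr61 is a matricellular protein and a known target of YAP. Those with lower values were Opcml (-0.64 ± 0.08), Cpz (-0.80 ± 0.11), Scx (-1.16 ± 0.16), Nlgn3 (-0.72 ± 0.10), Ppfibp2 (-0.78 ± 0.11), Wfdc18 (-1.54 ± 0.23), Tpd52l1 (-0.64 ± 0.10) and Tmc6 (-0.63 ± 0.10). Scx, the transcription factor scleraxis of tendon progenitors, stood at 44.6 ± 9.97 FPKM in controls and 19.2 ± 1.95 in treated libraries. In each of these 16 genes the groups did not overlap, and with a pseudocount of 0.1 the log2 fold change of Nlgn3 was -1.11.

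The heavy chains that blebbistatin targets did not pass the test. Myh9 stood at 179 ± 31.3 FPKM in controls and 161 ± 9.91 in treated libraries (log2 fold change -0.14 ± 0.14, adjusted p = 0.947), Myh10 at 52.1 ± 9.17 and 54.1 ± 4.72 (0.06 ± 0.14, adjusted p = 0.992), and Myh14 at 12.3 ± 1.82 and 8.70 ± 4.12 (-0.52 ± 0.25, adjusted p = 0.611). The log2 fold change of Myh10 turned negative without control replicate 1 (-0.055), without blebbistatin replicate 1 (-0.0051) and with array weights (-0.023). That of Myh9 was -0.28 without control replicate 1, -0.025 without control replicate 2, -0.091 without blebbistatin replicate 2 and -0.24 with array weights. Blebbistatin replicate 1 had 13.45 FPKM of Myh14, within the controls, and the log2 fold change was -0.85 without it and -0.345 without blebbistatin replicate 3. Of the 22 genes of myosin II subunits, their kinases and actin filament proteins, 17 had higher means, 0 passed, and the list itself did not pass (median log2 fold change 0.12, camera adjusted p = 0.0585).

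Genes activated by YAP and TAZ, transcriptional coactivators that respond to cell tension and shape, ranked above other genes. Of 17 tested members 15 had higher means, with a median log2 fold change of 0.36. None passed over all genes tested, and 8 passed when adjusted over the list alone, all of them higher. Crim1 went from 5.54 ± 0.40 to 10.1 ± 1.01 FPKM, Cyr61 from 29.6 ± 0.11 to 63.9 ± 14.6, Amotl2 from 7.38 ± 0.67 to 12.3 ± 2.42 and Ctgf from 27.0 ± 2.47 to 44.1 ± 9.91. The camera adjusted p was 5.86e-08, and the adjusted p was 0.525 with an estimated correlation. Without control replicate 3 the median was 0.23 and 5 members passed over the list alone. The score of the list was higher in all 3 treated libraries than in any control (exact permutation p = 0.1, the smallest possible).

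Genes activated by serum response factor (SRF) and its actin-regulated cofactors ranked higher as well. Of 21 members 17 had higher means, with a median log2 fold change of 0.12 (camera adjusted p = 0.00183, and adjusted p = 0.525 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone 2 passed, Tagln and Fhl2. Tagln, an actin-binding protein of contractile cells, stood at 238 ± 26.0 FPKM in controls and 365 ± 28.8 in treated libraries, and Fhl2 at 30.2 ± 0.94 and 41.3 ± 4.44. Filip1l (0.990 ± 0.10 and 2.02 ± 0.69) and Myl9 (309 ± 24.7 and 403 ± 50.5) did not pass over the list. The number past the list threshold was 4 without blebbistatin replicate 1, 0 without control replicate 2 and 1 without control replicate 3, and the median was 0.08 without blebbistatin replicate 2.

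Mitosis and cytokinesis genes ranked higher in the treated libraries, with the smallest p of any list for camera at the fixed correlation of 0.01, though not with an estimated correlation. All 24 members had higher means, between log2 0.28 and 0.54 with a median of 0.41, and the groups did not overlap for 19 of them. Over all genes tested 0 passed, and 17 passed when adjusted over the list alone. Aurka, a mitotic kinase, went from 21.6 ± 2.33 to 29.4 ± 2.05 FPKM, the cyclin-dependent kinase Cdk1 from 42.2 ± 4.56 to 56.0 ± 0.93, cyclin B2 (Ccnb2) from 31.8 ± 2.22 to 40.9 ± 1.07 and survivin (Birc5) from 58.5 ± 6.73 to 77.4 ± 4.57. The camera adjusted p was 4.26e-17, and the adjusted p was 0.525 with an estimated correlation, which was 0.867 among these genes. Control replicate 1 had the lowest score, -0.49, against 0.02 and -0.12 in the other controls and 0.26, 0.13 and 0.20 in treated libraries. Without control replicate 1 the median was 0.27, and without any 1 of the 3 treated libraries the count of 17 became 0.

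DNA replication genes ranked higher as a list. Of 20 members 19 had higher means, the median log2 fold change was 0.13, and 0 passed over all genes or when adjusted over the list alone (camera adjusted p = 8.56e-05, and adjusted p = 0.555 with an estimated correlation). Examples are Cdc45 (log2 fold change 0.32 ± 0.08, SE), Rrm2 (0.36 ± 0.11), Tyms (0.22 ± 0.08) and Slbp (0.20 ± 0.08). Without control replicate 2 the median was 0.20. Genes activated by p53 had a median of 0.20, with 13 of 16 means higher (camera adjusted p = 2.83e-05, and adjusted p = 0.525 with an estimated correlation). Over all genes 0 passed, and adjusted over the list alone Ccng1 (0.66 ± 0.12) and Sesn1 (0.38 ± 0.10) passed, while Trp53inp1 (0.44 ± 0.14) and Eda2r (0.56 ± 0.18) did not. The count of 2 for p53 targets was 1 without control replicate 2 or 3 or blebbistatin replicate 1 or 2, and 6 without blebbistatin replicate 3. The scores of the replication and p53 lists overlapped between the groups (exact permutation p = 0.2 for each).

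Genes of end buds and acinar progenitors ranked lower in treated libraries. Of 18 tested members 14 had lower means, with a median log2 fold change of -0.33. Over all genes 0 passed, and 7 passed when adjusted over the list alone, all lower. Agr2, a secretory pathway disulfide isomerase, stood at 7.06 ± 0.63 FPKM in controls and 3.24 ± 1.19 in treated libraries, Cldn10 at 228 ± 19.2 and 163 ± 6.92, the transcription factor Sox10 at 212 ± 5.42 and 143 ± 19.9, and the receptor kinase Kit at 30.1 ± 7.75 and 12.6 ± 6.28. The camera adjusted p was 2.15e-05, and the adjusted p was 0.525 with an estimated correlation. Blebbistatin replicate 1 had the lowest score, -0.42 against -0.06 in each of the other treated libraries, and without it the median was -0.18 and 4 members passed over the list. That count was 3 without control replicate 2 and 3 without control replicate 3. Sox10 is also on the list of Schwann cell genes, of which 3 of 12 were tested. Erbb3 on that list stood at 80.7 ± 8.04 and 53.1 ± 1.39 FPKM, and Ngfr at 20.3 ± 5.69 and 17.3 ± 5.19.

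Cartilage and bone genes ranked lower, through the collagens of types II and IX. Of 8 tested members 6 had lower means (median log2 fold change -0.30), 1 passed over all genes (Col2a1), and when adjusted over the list alone 4 were lower and 1 was higher. Col9a2 stood at 46.1 ± 9.40 FPKM in controls and 22.1 ± 3.16 in treated libraries, Col9a1 at 235 ± 18.3 and 153 ± 30.6, and Col9a3 at 267 ± 34.8 and 207 ± 16.1, and these 3 were lower over the list alone. The camera adjusted p was 0.00183, and the adjusted p was 0.525 with an estimated correlation. The median depended on the filter, with -0.15 over 17 members when no filter was used and -0.64 over 5 members with a minimum of 5 FPKM. The higher member, Col11a1 (1.18 ± 0.22 and 1.97 ± 0.49), did not pass over the list without control replicate 1 or 2 or without blebbistatin replicate 1 or 3, where that count was 0. Acan, the aggrecan core protein of cartilage, was at or below 0.0587 FPKM in all 6 libraries.

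TGF-beta and BMP ligands and target genes had 8 of 14 means lower and a median log2 fold change of -0.20 (camera adjusted p = 0.00636, and adjusted p = 0.525 with an estimated correlation). With no filter on low values the median over 20 members was -0.0080 (adjusted p = 0.047), and the list score overlapped between the groups (exact permutation p = 0.3). Over all genes 0 passed. Over the list alone the ligand Tgfb3 was higher, at 1.89 ± 0.23 FPKM in controls and 3.97 ± 0.64 in treated libraries. The ligand Tgfb1 (24.5 ± 4.36 and 12.2 ± 3.30), the BMP target Id2 (141 ± 8.23 and 99.1 ± 12.6) and the pseudoreceptor Bambi (2.28 ± 0.15 and 1.51 ± 0.31) were lower.

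**Figure D2:**
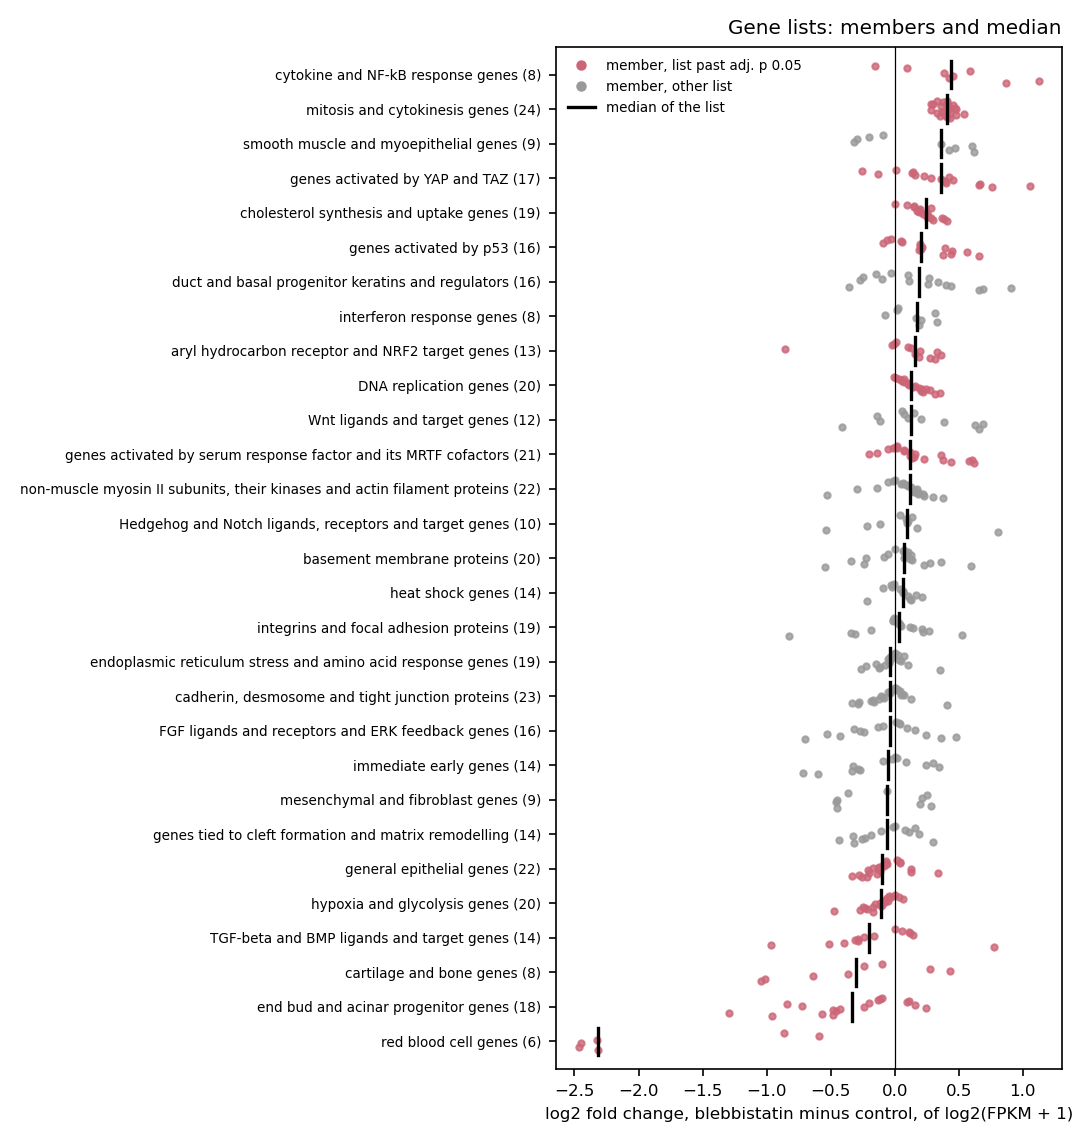
Log2 fold change of log2(FPKM + 1), blebbistatin minus control, of each tested member (points) of the 29 tested gene lists, with the median of each list as a black bar and the number of tested members in parentheses. Red marks the 14 lists past a camera adjusted p of 0.05, among which all 24 mitosis genes lie above 0, and 14 of 18 end bud genes lie below 0.

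**Figure D3:**
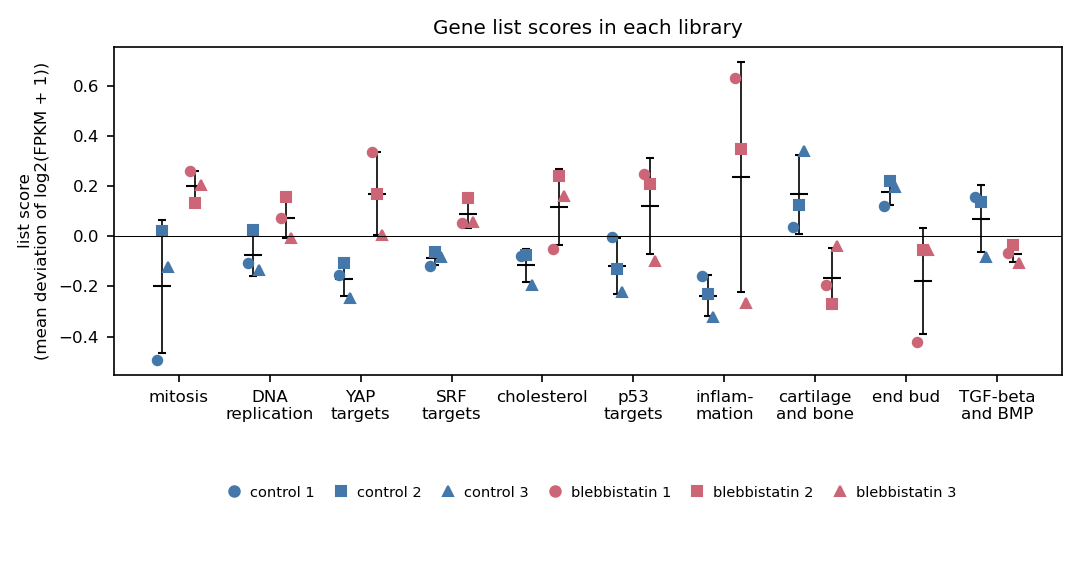
List score, the mean over tested members of the deviation of log2(FPKM + 1) from the mean of the 6 libraries, for 10 lists in each library, with bars giving mean and SD (n = 3). Treated libraries lie above all controls for mitosis, YAP targets, SRF targets and cholesterol, below all controls for cartilage and end bud, and overlap with controls for the other lists drawn.

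Cholesterol synthesis and uptake genes had higher means in all 19 tested members, with a median log2 fold change of 0.25 (camera adjusted p = 8.85e-08, and adjusted p = 0.525 with an estimated correlation). Neither over all genes nor when adjusted over the list alone did any pass. Examples are Nsdhl (0.41 ± 0.10, SE), Cyp51 (0.30 ± 0.10), Hmgcs1 (0.38 ± 0.13) and Insig1 (0.37 ± 0.13). Without blebbistatin replicate 1, 12 members passed over the list alone. Cytokine and NF-kB response genes had a median of 0.44 with 7 of 8 means higher (camera adjusted p = 0.00209, and adjusted p = 0.540 with an estimated correlation). Icam1, an adhesion molecule, was the 1 member past the list threshold (19.7 ± 1.82 FPKM in controls and 38.0 ± 12.2 in treated libraries), and 0 passed over all genes. Cxcl10 (log2 fold change 1.13 ± 0.42), Tnfaip3 (0.42 ± 0.18) and Relb (0.46 ± 0.22) did not pass. The score of this list was 0.63 and 0.35 in blebbistatin replicates 1 and 2 but -0.27 in blebbistatin replicate 3, within the controls. The count past the list threshold was 0 without any 1 of the controls or without blebbistatin replicate 1 or 2, and 6 without blebbistatin replicate 3. The median was 0.23 without blebbistatin replicate 1 and 0.66 without blebbistatin replicate 3, and the list did not pass with a minimum of 5 FPKM (0.24). With no filter the median was 0.14.

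Aryl hydrocarbon receptor and NRF2 target genes had a median log2 fold change of 0.16 with 10 of 13 means higher (camera adjusted p = 0.0253, and adjusted p = 0.656 with an estimated correlation), led by Gclc (0.32 ± 0.08, SE), Gclm (0.28 ± 0.09), Txnrd1 (0.19 ± 0.10) and Gstm1 (0.36 ± 0.19). Members of this list ranged from -0.86 to 0.36, so the largest change was a lower value. Hypoxia and glycolysis genes had a median of -0.10 with 18 of 20 means lower (camera adjusted p = 0.0145, and adjusted p = 0.656 with an estimated correlation), led by Hk1 (-0.17 ± 0.08), Ankrd37 (-0.47 ± 0.25), Pfkl (-0.27 ± 0.16) and Pkm (-0.21 ± 0.14). General epithelial genes had a median of -0.10 with 16 of 22 means lower (camera adjusted p = 0.0253, and adjusted p = 0.681 with an estimated correlation), led by Esrp2 (-0.25 ± 0.12), Rab25 (-0.22 ± 0.10), Cldn6 (-0.34 ± 0.19) and Cldn3 (-0.28 ± 0.16). In these 3 lists 0 members passed over all genes or when adjusted over the list alone, and list scores overlapped between the groups. The aryl hydrocarbon receptor and NRF2 call was lost without control replicate 2 (median 0.11), control replicate 3 (0.09) or blebbistatin replicate 1 (0.09), and the epithelial call without control replicate 1 (-0.07), control replicate 2 (-0.07) or blebbistatin replicate 3 (-0.04). The hypoxia call was lost without control replicate 1 (-0.09), control replicate 2 (-0.04), blebbistatin replicate 1 (-0.04) or blebbistatin replicate 3 (-0.02), and with array weights, where the median was 0.0003. With no filter on low values the hypoxia, epithelial and red blood cell lists did not pass. Medians were more than 1.5 times as large for aryl hydrocarbon receptor and NRF2 targets without control replicate 1 (0.30) or blebbistatin replicate 3 (0.27), for hypoxia genes without control replicate 3 (-0.19) or blebbistatin replicate 2 (-0.20), and for epithelial genes without control replicate 3 (-0.18) or blebbistatin replicate 1 (-0.18). Over the list alone, 4 aryl hydrocarbon receptor and NRF2 targets passed without control replicate 1, and 1 hypoxia gene passed without blebbistatin replicate 2.

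Red blood cell genes varied between libraries. The summed FPKM of globin genes was 307, 1.97 and 277 in control replicates 1 to 3, and 1.14, 7.22 and 78.7 in blebbistatin replicates 1 to 3. The red blood cell list had a median log2 fold change of -2.32 with 6 of 6 means lower (camera adjusted p = 0.0145, and adjusted p = 0.638 with an estimated correlation), with 0 members past the threshold over all genes or adjusted over the list alone. The adult globin genes Hbb-bt (20.6 ± 20.2 and 1.83 ± 2.78 FPKM), Hbb-b1 (36.5 ± 42.8 and 2.89 ± 4.48), Hba-a2 (28.0 ± 27.2 and 3.10 ± 5.35) and Hba-a1 (89.5 ± 77.5 and 15.3 ± 22.8) share sequence, and the annotated loci of the last pair overlap. The call was lost without control replicate 1 (median -1.22), control replicate 3 (-1.40) or blebbistatin replicate 1 (-1.59) and with no filter (-0.46), and without control replicate 2 the median was -4.05 and 4 members passed over the list alone. Of mesenchymal genes 9 of 22 were tested, with a median of -0.06 (camera adjusted p = 0.697), and their score was highest in control replicate 1 (0.44, against -0.20 to 0.07 in the other libraries). Tested members numbered 1 of 16 for endothelium, 1 of 19 for neurons, 2 of 16 for leukocytes and 2 of 21 for skeletal muscle, with 0 past the threshold.

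The other 13 tested lists beside the myosin and actin list and the mesenchymal list did not pass (camera). Median log2 fold changes were 0.36 for smooth muscle and myoepithelial genes (adjusted p = 0.115), 0.19 for duct and basal progenitor genes (adjusted p = 0.110) and 0.18 for interferon response genes (adjusted p = 0.302). They were 0.13 for Wnt genes (adjusted p = 0.138), 0.09 for Hedgehog and Notch genes (adjusted p = 0.561), 0.08 for basement membrane proteins (adjusted p = 0.524) and 0.06 for heat shock genes (adjusted p = 0.561). Integrins and focal adhesion proteins had a median of 0.03 and a mean of -0.0013 (adjusted p = 0.930). Medians were -0.03 for endoplasmic reticulum stress genes (adjusted p = 0.428), -0.04 for cell junction proteins (adjusted p = 0.215), -0.04 for FGF and ERK genes (adjusted p = 0.454), -0.05 for immediate early genes (adjusted p = 0.081) and -0.06 for cleft and matrix remodelling genes (adjusted p = 0.145). With an estimated correlation 0 of the 29 lists passed after adjustment and 1 passed before it, the end bud list. With fry, 0 lists passed as moving one way on balance, and 6 passed as changing in either direction (YAP targets, SRF targets, end bud, cartilage, TGF-beta and BMP, and smooth muscle and myoepithelial genes). The smooth muscle list shares members with the SRF list, Tagln and Acta2 among them, and over the list alone Tagln and Synpo2 passed, both higher. Every other split of the 6 libraries into 3 and 3 also had lists past the threshold (camera), from 4 to 15 of them, against 14 for the treatment.

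At the level of transcripts, 1 of 14460 passed an adjusted p of 0.05 (limma), the lower transcript of Mir8094, and 1169 had an unadjusted p under 0.05. The next 6 by p belonged to genes already named. The transcript of 1810010H24Rik had an adjusted p of 0.074, those of Tnc, Slc35f1, Olfml3 and Fam101a 0.153 each, and that of Lurap1l 0.155. The count of transcripts was 2 without control replicate 2, 12 without control replicate 3, 2 without blebbistatin replicate 2 and 3 without blebbistatin replicate 3. It was 9 with no filter, 2 with a minimum of 5 FPKM, and 3 after quantile normalization (1 higher, 2 lower, against 0 higher and 1 lower as deposited).

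Isoform shares did not differ past the threshold. Of 4997 transcripts in 2103 genes, 0 passed an adjusted p of 0.05 (limma on the arcsine square root of the share). An unadjusted p under 0.05 was found for 233, which is not more than chance alone would give. Transcripts of the same gene are counted separately there, although their shares depend on each other. The smallest adjusted p, 0.175, belonged to a transcript of Kifc3, a kinesin, NM_001145832, whose share was 10.6 ± 2.28% in controls and 0.108 ± 0.17% in treated libraries (SD, n = 3). The other transcripts of smallest p had an adjusted p of 0.962. Capn5 transcript NM_007602 took 72.7 ± 4.07% and 92.6 ± 4.73%, with NM_001301250 as its complement (27.3 ± 4.07% and 7.39 ± 4.73%). Slc37a4 transcript NM_001293631 took 21.3 ± 2.52% and 35.6 ± 4.20%. In Dst, which encodes a cytoskeletal linker, NM_133833 took 30.1 ± 3.94% and 17.5 ± 1.52%, and NM_010081 took 54.5 ± 6.44% and 72.5 ± 2.58%, while the summed FPKM of Dst was 3.41 and 7.77. The count of 0 became 2 without control replicate 2 and with a gene minimum of 1 FPKM.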

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

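Removal of the trend with transcript length, alone or with the block, was tested only after the data were seen, and all other settings were chosen before. Across 17 settings the 8 named calls kept their direction, and each passed the threshold in 9 to 12 of them (Slc35f1 and Fam101a were not tested with a minimum of 5 FPKM). The call of Mir8094 was lost in 1, where small RNA genes were left out by construction. Of the 14 lists, 9 passed in all 17 settings (mitosis, DNA replication, YAP, SRF, p53, cholesterol, end bud, cartilage, TGF-beta and BMP). All 17 keep the fixed correlation of 0.01, and with an estimated correlation 0 of the 14 lists passed. The 5 others were lost in 1 to 6 settings, and the count of lists ranged from 11 to 18 over the libraries left out. The cause of the differences between settings was not tested, except that leaving libraries out takes away residual degrees of freedom and a filter changes the number of tests. At 54.6 to 66.5 fragments per FPKM at 2 kb, a gene at the limit of 1 FPKM rests on about that many fragments.

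Against 9 genes, no filter gave 1, a minimum of 5 FPKM 27, median-of-ratios rescaling 2, quantile normalization 14, array weights 57 and removal of the length trend 18. Leaving out each library gave 1 to 19. Against 4 genes with an absolute log2 fold change of at least 1, a pseudocount of 0.1 gave 8, no filter 1, the minimum of 5 FPKM 10, median-of-ratios rescaling 1 and array weights 15. Leaving out each library gave 1 to 15, with 1 without control replicate 1, 2 without control replicate 2, 2 without blebbistatin replicate 1 and 15 without blebbistatin replicate 3. Against 1 transcript, no filter gave 9, the minimum of 5 FPKM 2, quantile normalization 3, and leaving out each library 1 to 12. Against 0 transcript shares, a gene minimum of 1 FPKM gave 2, and leaving out each library 0 to 2. The log2 fold change of Myh10 (0.06) turned to -0.023 with array weights, and over the libraries left out it ranged from -0.055 to 0.19.

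The replicate numbers are shared between groups, but nothing in the labels says that they pair the samples. Deviations from the group means correlated by 0.182, 0.094 and 0.253 for replicates 1 to 3, not above 0.1 in every pair, so they were not taken as pairs. With the length trend removed, a step added after the data were seen, they were 0.213, 0.145 and 0.264, all above 0.1, so pairing stays possible. In these deviations every library correlated best with its own number in the other group, a hint from the data and not the design. With the replicate block, 144 genes passed, 20 of them with an absolute log2 fold change of at least 1, and 16 lists. With the block and the length trend removed, 300 genes passed, 24 of them with an absolute log2 fold change of at least 1, and 0 transcripts.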

Other observations

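The tests in this part, other than leaving out each library, were chosen after the data were seen. Genes that share a symbol stem were tested as families with camera, leaving out genes on the lists already described. Of 120 families with at least 10 tested members, 4 passed an adjusted p of 0.05, and 0 passed with an estimated correlation (adjusted p = 0.982 for each of the 4). Nucleoporins (Nup), the proteins of nuclear pores, had 18 of 19 means higher under blebbistatin, with a median log2 fold change of 0.15 (adjusted p = 0.00387). Examples are Nup37 (0.27 ± 0.08, SE) and Nup35 (0.23 ± 0.08). Kinesins (Kif) had 18 of 25 means higher and a median of 0.11 (adjusted p = 0.0177), led by the mitotic kinesins Kif2c (0.36 ± 0.10) and Kif18a (0.35 ± 0.10). Semaphorins (Sema), which are guidance cues, had 11 of 13 means lower and a median of -0.14 (adjusted p = 0.0155), led by Sema4a (-0.50 ± 0.09) and Sema6a (-0.39 ± 0.10). In these 3 families 0 genes passed over all genes tested. The 3 medians kept their sign under median-of-ratios and quantile scaling, with the length trend removed and without each library in turn. Over the libraries left out they ranged from 0.08 to 0.23 for Nup, 0.09 to 0.19 for Kif and -0.18 to -0.10 for Sema.

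The mitosis list ranked higher in the treated libraries (camera, with an adjusted p = 0.525 with an estimated correlation), by a score difference of 0.398, with a pooled SD of 0.192. The libraries differed in a trend with transcript length. Its Spearman correlation across genes was -0.502, 0.441 and 0.199 in control replicates 1 to 3, and 0.046, -0.041 and 0.083 in blebbistatin replicates 1 to 3. The trend thus did not follow the groups, so that removing it could hardly move a group difference and is a weak test. After its removal the score difference was 0.391 with an SD of 0.178. Without control replicate 1 it was 0.251 with an SD of 0.0773, so that this library alone does not account for it, although it sets part of the size. A candidate explanation is that cells were held in mitosis, which would raise mitosis genes above replication genes. The mitosis score minus the replication score differed by 0.251 between groups (exact permutation p = 0.3, smallest possible 0.1). It was -0.385, -0.0042 and 0.012 in control replicates 1 to 3, and 0.187, -0.021 and 0.21 in blebbistatin replicates 1 to 3. Control replicate 1 thus sets part of this difference too. With 3 libraries per group, cells held in mitosis and a larger share of cycling cells cannot be told apart.

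The lists of YAP and SRF targets ranked higher (camera, with an adjusted p = 0.525 for each with an estimated correlation), although myosin II, which generates the tension that both respond to, was the target of the compound. The joint score of 38 members differed by 0.249 with a pooled SD of 0.0624, and by 0.242 with an SD of 0.0395 after removal of the length trend. As that trend did not follow the groups, its removal could hardly move the difference and decides little. Without blebbistatin replicate 1 the difference was 0.221 with an SD of 0.0602, which argues against that library as the whole cause. Mesenchymal cells would bring collagens. The summed FPKM of Col1a1, Col1a2 and Col3a1 was at most 4.75 in a treated library (2.91 to 13.7 in controls). The summed gain was 608 FPKM over the list members, which argues against cells rich in these collagens as the source. Of the 9 tested mesenchymal genes 4 had higher means, Vim (305 ± 30.7 and 350 ± 21.1 FPKM) among them, and 5 had lower means. Mesenchymal cells without these collagens are therefore not excluded. What stays open, as untested, is a different share of contractile cells, a response of the epithelium to the treatment and the effect of dose, time or vehicle, which the labels do not give.

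The cartilage and bone list and the end bud list both ranked lower (camera, with an adjusted p = 0.525 for each with an estimated correlation), by a joint score difference of -0.35 with a pooled SD of 0.124. After removal of the length trend it was -0.354 with an SD of 0.137, a weak test here too, since that trend did not follow the groups. Cartilage in the control samples would bring aggrecan and matrilin, and the sum of Acan and Matn1 was at most 0.059 FPKM in a control, 0.067% of the 87.1 FPKM by which Col2a1 was lower, which argues against carried-over cartilage. A candidate explanation is a smaller share of end bud cells against duct cells. The duct and basal score minus the end bud score differed by 0.545 between groups (exact permutation p = 0.2, smallest possible 0.1), with 0.839 in blebbistatin replicate 1, 0.05 and -0.071 in the other treated libraries and up to 0.00026 in controls. A smaller share of end bud cells and a lower expression within them cannot be told apart with these libraries.

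The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. For genes, the treatment gave 9 and the highest other split 1, and 1 of the 10 splits, the treatment itself, gave as many. For genes with an absolute log2 fold change of at least 1 the treatment gave 4 and the highest other split 1, and again 1 split gave as many. For lists it was 14 against 15 (2 splits with as many, the treatment included), for transcripts 1 against 2 (4 splits) and for transcript shares 0 against 2 (10 splits). Every other split had at least 4 lists past the threshold.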
